A study of Arabidopsis thaliana with 6 samples.

How the data were processed

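The series measured transcript levels in whole rosettes of the Arabidopsis thaliana pgm mutant in the Col-0 background, a line without plastidic phosphoglucomutase that makes almost no starch. Total RNA was labelled with biotin, per the labels' protocols, and hybridised to single-colour Affymetrix arrays. There were 6 arrays in 3 groups of 2 biological replicates, called A and B in the labels, and every group had been treated for 4 hours: low CO2 in prolonged darkness, low CO2 in light, and normal CO2 in light. The rosettes were 5 to 6 weeks old.

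The deposited values are linear intensities, 1 per probe set, and the submitters' processing notes name MAS5. The version, the scaling target and detection calls are not given in the sources used here. The mean intensity after trimming 2% of the probe sets at each end lay at 100.01 on each array, so the arrays had been scaled to each other before deposit, and no normalization was added. Median intensities ran from 34.6 to 39.55. Single-colour arrays carry no count of molecules, so the number of arrays limits the precision.

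The table held 22810 probe sets, of which 64 were controls and 22746 were tested. Gene names came from the platform annotation supplied with the values, checked by Entrez ID against the TAIR10.1 gene table, which was used for names alone. A single gene symbol was given for 13513 probe sets, several for 503 and none for 8730, and 13436 of the single names matched by Entrez ID, with 0 symbols changed. No gene was named from a probe set with several symbols. Many widely studied genes have no named probe set here, among them PGM1, the mutated gene, which is therefore not analysed here. The symbol PGM on the array belongs to another gene.

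Values were transformed as log2(intensity + 7.3), where 7.3 is the 20th percentile of all tested values, so fold changes of dim probe sets are understated. One linear model with 3 group means was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend), which left 3 residual degrees of freedom and gave 3.27 prior degrees of freedom. The contrasts were the light step (low CO2 in light minus low CO2 in darkness), the CO2 step (normal CO2 in light minus low CO2 in light), their sum, and the CO2 step minus the light step. Benjamini-Hochberg adjustment ran over the 22746 probe sets, with a threshold of 0.05 on the adjusted p and no fold minimum. All adjusted p-values of genes come from this limma model. The 2 replicates are named biological in the series text.

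The rule for named genes was fixed before the data were examined: per contrast, the 10 genes with the largest rise and the 10 with the largest fall among named probe sets past the threshold with both arrays of one group above both of the other, and per gene list up to 3 members past the threshold with the largest change, or the 2 with the smallest p where none passed, with the reference genes always given. Where a list is described by its test alone, its members are summarised. Genes named for the difference between the steps were taken as the 10 largest per direction, a rule chosen after the data were seen.

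A total of 30 gene lists with 426 distinct genes were written before the data were examined, and 74 of these genes were named by a probe set. Lists with at least 3 measured genes numbered 14 and were tested with camera (preset correlation 0.01), adjusted over the lists and the 3 contrasts, with 1 probe set per gene, the one with the highest mean. The lists of dark and starvation induced genes, trehalose metabolism, nitrate and ammonium assimilation, carbonic anhydrases, phloem markers, and flower and bolting markers had 0 measured genes and gave no result. A further 10 lists (cytosolic ribosomal proteins, ribosome biogenesis factors, cytosolic aminoacyl-tRNA synthetases, translation initiation and elongation factors, oxidative pentose phosphate pathway, core histones, small heat shock proteins, CC-type glutaredoxins, plastid-encoded genes and mitochondrion-encoded genes) were written after the data had been seen, from gene names and not from the members' values, and formed a separate family of tests. Families of genes that share a symbol prefix, 37 in number, formed another.

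Both the model and the list test were tested on simulated data with the real means and spreads of the 22746 probe sets. Changes of 1 on the log2 scale were recovered in 37% of cases in the light step, 37% in the CO2 step, 43% in the sum and 0% in the difference between the steps. Changes of 2 were recovered in 95%, 98%, 93% and 24%. Each simulation changed 100 probe sets of each size. Recovery after Benjamini-Hochberg adjustment depends on how many probe sets change. These rates therefore do not give the power of the real CO2 step, where 14.6% of probe sets were called, and do not show equal power in both steps. A shift of 0.5 given to 113 cytosolic ribosomal protein genes in the CO2 step was called, with 0 of 61 lists called in the light step. The simulated noise was independent between genes, whereas this list had an estimated correlation of 0.401 in the data. The 0 of 61 therefore does not measure false calls among lists whose genes vary together.

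The alternatives were quantile normalization, arrays shifted to a common median, no pseudocount (values floored at 0.1), a pseudocount at the 40th percentile (21.8), a filter at the 40th percentile of mean log2 intensity, no trend in the variance prior, a model of the 2 groups compared, the replicate letter as a block, a minimum log2 fold change of 1, and each array left out in turn. For gene lists, camera with an estimated correlation, fry and averaging of all probe sets of a gene were also run, and the common median was added after the data were seen. Camera with an estimated correlation rests on the 3 residual degrees of freedom, so a list can fail it through the small number of arrays alone. Python 3.11.15 and matplotlib 3.10.9 drew the figures.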

Results

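Transcript levels were measured on 6 arrays from whole rosettes of the starchless pgm mutant, 2 per treatment. The 3 treatments formed a series of 2 steps: from darkness to light at low CO2, called the light step here, and from low to normal CO2 in light, called the CO2 step. The title of the series names light and endogenous sugar from carbon fixation as the matters studied. Replicates A and B of one group correlated with r = 0.971 across probe sets for low CO2 in light, 0.984 for normal CO2 in light and 0.978 for low CO2 in darkness. The bacterial bioC spike-in read 66.3 to 73.8 on the 3 arrays of replicate A and 116.2 to 157.3 on those of replicate B. The letter therefore marks a difference between arrays that is not one of treatment, and each letter holds all 3 groups. Ratios of 3 prime to 5 prime controls were taken from the second set of plant controls, named r2. That of ubiquitin was 1.69 and 1.95 on the arrays of normal CO2 and 1.38 to 1.48 on the 4 arrays of low CO2. The GAPDH ratio lay between 0.949 and 1.13 on all arrays. It was higher in the first set, with 882.1 over 481.8 on low CO2 in light A against 1038.1 over 1019.1 in the second.

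Light at low CO2 raised transcripts of AT3G44450 and AT3G52740, which encode BIC proteins that inhibit the blue-light receptor cryptochrome. AT3G44450 rose from an intensity of 12.6 ± 0 (SD, n = 2) in darkness to 160 ± 39.7 (n = 2), a log2 fold change of 3.05 ± 0.22 (SE, adjusted p = 0.0142). AT3G52740 rose by 2.32 ± 0.34 (adjusted p = 0.0446). ATSPS4F (AT4G10120), a sucrose phosphate synthase, rose 5.15-fold, from 81.5 ± 21.4 to 448 ± 91.4 (adjusted p = 0.0172). The transcripts that fell included WES1, a GH3 enzyme that conjugates auxin to amino acids, from 351 ± 68.5 to 105 ± 13.6 (log2 fold change -1.67 ± 0.19, adjusted p = 0.0277). UGT72E1, a glucosyltransferase of phenylpropanoid aldehydes, fell too (-1.45 ± 0.16, adjusted p = 0.0254).

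Among named genes, the largest rises of the light step were in AT1G70820 (log2 fold change 3.75), AT4G16880 (3.69), AT4G12830 (3.47) and AT5G42250 (3.42). They were followed by AT3G44450 (3.05), AT5G38510 (2.95), AT1G62510 (2.95), ATSPS4F (2.36) and AT5G59130 (2.35). AT5G12050, AT2G44850 and AT1G21830 fell, with log2 fold changes of -2.40, -1.80 and -1.74, and AT2G28400 fell from an intensity of 386.7 to 84.7. The serine-rich salt-induced gene SIS (AT5G02020) fell from 1388 ± 205 to 449 ± 110 (-1.62). AT1G30200, AT4G23760 and AT3G07350 had log2 fold changes of -1.34, -1.24 and -1.21, all past the threshold. AT4G23760 went from an intensity of 12 to 0.9 and AT4G16880 started from 5.85. So near the pseudocount of 7.3, the sizes of both changes depend on it. In the whole array, 193 probe sets rose and 44 fell in the light step, 1.04% of those tested. Of all, 3758 had an unadjusted p under 0.05. With limma the count was 0 higher and 0 lower in a model of the 4 arrays of these groups (3445 at unadjusted p), without normal CO2 in light replicate A (3442) and without replicate B of that group (3435). It was 1 and 0, 4 and 0, 88 and 11, and 5 and 1 without low CO2 in light A, low CO2 in darkness A, low CO2 in light B and low CO2 in darkness B. With the replicate letter as a block it was 338 and 137.

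Of the lists fixed in advance, 2 were called in the light step. That of sucrose metabolism and sugar transport shifted up (median log2 fold change 0.65, camera adjusted p = 0.0219, and adjusted p = 0.568 with an estimated correlation). It had 1 of 3 measured members past the threshold over all probe sets and 2 adjusted over the list alone. Beside ATSPS4F, the vacuolar invertase AT1G62660 had 0.65 and SWEET11 -0.02, both short of the threshold. Starch synthesis and breakdown shifted up as well (median 0.28, adjusted p = 0.0408, and adjusted p = 0.568 with an estimated correlation). The branching enzyme SBE2.2 (AT5G03650) rose by 0.83 ± 0.13 (adjusted p = 0.0493), the single member of 5 to pass. Adjusted over the list alone it was also 1 of 5. The starch list had a median of 0.52 in replicate A and 0.66 in replicate B, and its adjusted p was 0.0521 with fry and 0.0626 after the filter on dim probe sets. Left-out arrays ended the call of the starch list at adjusted p = 0.144 (low CO2 in light A), 0.0519 (normal CO2 in light A), 0.0671 (normal CO2 in light B) and 0.162 (low CO2 in darkness B, median 0.43). Without low CO2 in darkness A its median was 0.59 (adjusted p = 0.0362). The call of the sucrose list ended at 0.144, 0.0504 and 0.0664 for the first 3 of these arrays.

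The lists of light-harvesting, photosystem, Calvin-Benson and photorespiration genes, fixed in advance, gave no camera call in the light step. In that order 3 of 19, 4 of 21, 4 of 19 and 3 of 15 genes were measured, so most of their genes were not assessed. Of the light-harvesting proteins, LHCB4.3 had a log2 fold change of 1.28 (adjusted p = 0.0517) and LHCB4.2 of -0.27. This list had a median of -0.10 where its mean was 0.31 and the test pointed up (adjusted p = 0.810), and the median was 0.01 after quantile normalization. The photosystem core list, with PSAE-1 at -0.12 and PSAN at -0.08, had a median of -0.06 (adjusted p = 0.806). The Calvin-Benson cycle, with SBPASE at 0.40 and AT5G64380 at 0.24, had 0.26 (adjusted p = 0.210), and photorespiration, with AT1G80380 at 0.49 and AT1G11860 at 0.36, had 0.36 (adjusted p = 0.187). Each of these lists had 0 members past the threshold. GI, the clock gene GIGANTEA, had 2.18 ± 0.39 (adjusted p = 0.0621), and the light-signalling factor HYH 0.74 (adjusted p = 0.332). XTH16, a cell wall xyloglucan endotransglucosylase, rose by 1.16 (adjusted p = 0.0393). It was the single one of 5 expansins and xyloglucan endotransglucosylases to pass (list adjusted p = 0.661). Of the lists written after the data had been seen, cytosolic ribosomal proteins shifted down (median -0.20, camera adjusted p = 1.69e-07, and adjusted p = 0.688 with an estimated correlation). Its adjusted p was 0.343 with fry. Its median was -0.11 without low CO2 in darkness B, -0.13 without low CO2 in light A and -0.31 without low CO2 in darkness A or low CO2 in light B. Over all probe sets 0 of its 113 members passed in limma, and 0 adjusted over the list alone. Cytosolic aminoacyl-tRNA synthetases had -0.16 (adjusted p = 0.0413, and adjusted p = 0.688 with an estimated correlation). That call ended with fry (0.276), quantile normalization (0.132), a common median (0.0583) and the filter on dim probe sets (0.207). It also ended without low CO2 in light A (0.0632) or B (0.0793), normal CO2 in light A (0.0542) or B (0.0597), or low CO2 in darkness B (0.488, median -0.02). Without low CO2 in darkness A the median was -0.31. Plastid-encoded genes had 0.18 (adjusted p = 0.0126, and adjusted p = 0.853 with an estimated correlation and 0.647 with fry), but -0.05 in replicate A against 0.34 in replicate B. Without low CO2 in light B the median was -0.04 (adjusted p = 0.552) without low CO2 in darkness A it was 0.12 (adjusted p = 0.0878), and without low CO2 in light A it was 0.36.

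**Figure D1:**
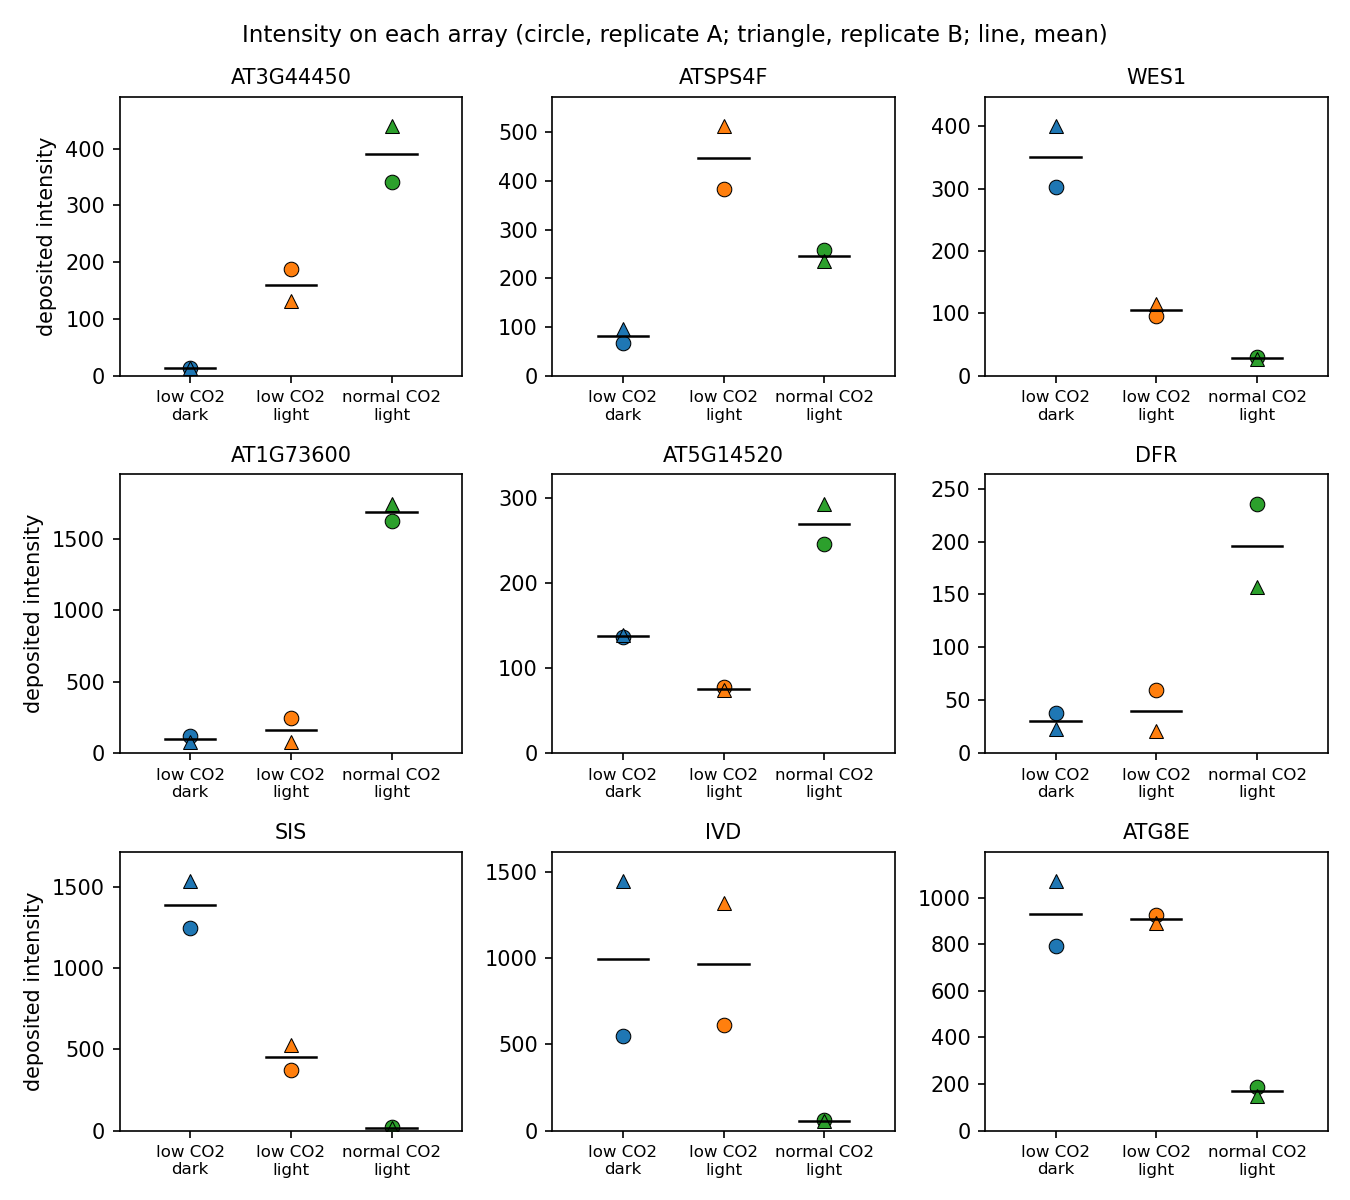
Deposited intensity of 9 genes on each of the 6 arrays, with the treatment on the horizontal axis, replicate A as circles, replicate B as triangles and the mean of 2 arrays as a line; vertical axes start at 0. AT3G44450 was highest at normal CO2 in light, WES1 highest in darkness, and IVD and ATG8E were low at normal CO2, with IVD at 58.5 and 55.1 there.

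At normal CO2 in light, relative to low CO2 in light, ATG8E (AT2G45170), one of the ATG8 proteins that coat autophagosomes, fell from 910 to 168 (log2 fold change -2.39 ± 0.19, n = 2 per group, adjusted p = 0.00485). IVD (AT3G45300), isovaleryl-CoA dehydrogenase of leucine breakdown, fell from 965 ± 498 (SD, n = 2) to 56.8 ± 2.40, a log2 fold change of -3.82 ± 0.51 (adjusted p = 0.00995). The Pescadillo homologue AT5G14520, a factor of large ribosomal subunit assembly, rose from 75.7 to 270.1 (1.74 ± 0.14, adjusted p = 0.00485). AT1G73600, a phosphoethanolamine N-methyltransferase gene of phosphocholine synthesis, had the largest rise among named genes, from 162 ± 118 to 1686 ± 83.9 (3.52 ± 0.49, adjusted p = 0.0105).

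Other large rises of the CO2 step were those of GH9C2, a family 9 glycosyl hydrolase (log2 fold change 3.14), AT1G04040 (3.03), TBL26 (2.53), AT5G64670 (2.52), AT5G62210 (2.49), AT2G34357 (2.45), AT3G54400 (2.41) and AT4G32605 (2.36), and AT4G38100 rose from 23.6 to 167.8. AT1G04040, AT5G64670, AT5G62210, AT2G34357 and AT4G32605 started from dim and variable values at low CO2 in light, such as 18.6 ± 21.4 (SD, n = 2) for AT1G04040. The change of AT1G04040 was 1.74 in replicate A and 4.32 in replicate B, and that of AT5G62210 1.46 and 3.52. The sizes of these rises are therefore uncertain. SIS had the largest fall among named genes, to 16.9 ± 4.31 (log2 fold change -4.23). AT2G05540, AT1G72060, AT5G19120, AT3G15630 and AT1G05340 fell as well, with -4.09, -4.07, -3.96, -3.94 and -3.90. AT2G32150, AT2G20670 and AT1G09500 fell with -3.73, -3.62 and -3.61. In all, 1911 probe sets rose and 1410 fell, 14.6% of those tested, of which 1037 and 893 changed at least 2-fold. The median size of the called changes was 0.96 in replicate A and 1.21 in replicate B. With arrays shifted to a common median the split was 1574 higher and 1742 lower, and with the letter as a block it was 2273 and 1687. The arrays of normal CO2 also had the higher ubiquitin 3 prime to 5 prime ratios (1.69 and 1.95 against 1.38 and 1.44 at low CO2 in light). Their actin ratios, also from the second set of controls, were 2.16 and 2.60, against 2.63 and 2.84 at low CO2 in light and 1.97 and 2.34 in darkness. In the first set the actin ratio was instead higher at normal CO2 than at low CO2 in light, with a dim 5 prime probe set. There A and B read 744.8 over 129.2 and 708.9 over 71.5, against 458.5 over 97.5 and 377.5 over 81.2 at low CO2 in light. In darkness they read 447.9 over 125.8 and 417.6 over 56.3, so the ratio of darkness B was above that of normal CO2 in light A. With limma 0 probe sets passed in either direction without normal CO2 in light A (5835 at unadjusted p under 0.05) or without its replicate B (4779), and 567 rose and 646 fell without low CO2 in light B.

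Of the 8 measured autophagy genes, 7 fell and 8 of 8 fell when adjusted over the list alone. The largest falls beside ATG8E were in ATG8H (-2.17 ± 0.30, adjusted p = 0.0103) and APG8A (AT4G21980; -1.38 ± 0.15, adjusted p = 0.00712), while ATG8G had -0.65 (adjusted p = 0.0927 over all probe sets). The list had a median of -1.30 (camera adjusted p = 3.19e-06, and adjusted p = 0.568 with an estimated correlation), with -1.14 in replicate A and -1.34 in replicate B. Branched-chain amino acid and proline breakdown shifted down with a median of -1.65 (camera adjusted p = 0.00112; -1.12 in A and -2.22 in B). It had an adjusted p = 0.568 with an estimated correlation, and 0.0675 with fry. Of its 6 members, 3 fell over all probe sets and 6 adjusted over the list alone. MCCA (AT1G03090), a subunit of methylcrotonyl-CoA carboxylase in leucine breakdown, fell by 3.34 ± 0.69 (adjusted p = 0.0274) and D2HGDH, a hydroxyglutarate dehydrogenase of lysine breakdown, by 0.85 ± 0.14 (adjusted p = 0.0153). No array left out in turn ended the call of either list, with adjusted p up to 8.84e-05 for autophagy and 0.0147 for breakdown.

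Ribosomal and nucleolar proteins, the third list fixed in advance to be called, shifted up by a median of 0.98 (camera adjusted p = 0.00112, and adjusted p = 0.568 with an estimated correlation). Over all probe sets 4 of 6 members rose, and 5 adjusted over the list alone, led by AT3G05060 (1.69 ± 0.23, adjusted p = 0.0105), AT3G04840 (1.37 ± 0.17, adjusted p = 0.00914) and AT5G02870 (1.08 ± 0.18, adjusted p = 0.0158). The following lists were written after the data had been seen. Of 113 cytosolic ribosomal protein genes 65 rose and 0 fell, and 90 rose adjusted over the list alone (median 0.86, adjusted p = 3.45e-27, and adjusted p = 0.657 with an estimated correlation), led by AT3G16780 (2.05), AT3G57490 (2.03) and AT4G30800 (1.90). Of 21 ribosome biogenesis factors 20 rose (median 1.64, adjusted p = 8.89e-14, and adjusted p = 0.657 with an estimated correlation), led by AT2G40360 (2.04), AT3G15460 (2.00) and AT3G58660 (1.99). Cytosolic aminoacyl-tRNA synthetases shifted up with 6 of 12 members past the threshold (median 0.66, adjusted p = 4.00e-05, and adjusted p = 0.657 with an estimated correlation), among them AT4G39280 (1.02), AT5G26830 (0.90) and AT3G02760 (0.82). Core histones did so with 4 of 8 (median 0.69, adjusted p = 0.00153, and adjusted p = 0.657 with an estimated correlation), among them HTB1 (1.61), HTB2 (1.59) and AT5G02570 (0.99). Core histones had an adjusted p = 0.0509 after the filter on dim probe sets. The medians of these 4 lists in replicates A and B were 0.81 and 0.87, 1.35 and 1.74, 0.66 and 0.70, and 0.50 and 0.90.

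Single genes of other lists also passed in the CO2 step. DFR and UF3GT, the 2 measured genes of phenylpropanoid and flavonoid synthesis, act late in anthocyanin formation and rose by 2.21 ± 0.45 (adjusted p = 0.0265) and 2.21 ± 0.43 (adjusted p = 0.0234). Of sulfate assimilation, APS3 (an ATP sulfurylase) rose by 1.59 ± 0.19 and SIR (sulfite reductase) by 1.35 ± 0.25 (adjusted p = 0.00825 and 0.0196), in a list with adjusted p = 0.187. STZ, a zinc-finger repressor of stress responses, fell by 2.65 ± 0.21 (adjusted p = 0.00485), and SAPX, a stromal ascorbate peroxidase, rose from 109.5 to 308 (adjusted p = 0.0138). Their list of oxidative and heat stress was not called (adjusted p = 0.841). WRKY6, a transcription factor of senescence, fell by 1.94 ± 0.29 (adjusted p = 0.0121). PPDK, pyruvate orthophosphate dikinase, fell by 1.75 ± 0.33 (adjusted p = 0.0215), and the vacuolar invertase AT1G62660 by 0.72 ± 0.13 (adjusted p = 0.0212). The list of PPDK, glycolysis and organic acids, had a median of 0.07, a mean of -0.46 and a test that pointed down (adjusted p = 0.832), and that of the invertase an adjusted p = 0.352. EXPA4 and XTH16 rose by 0.87 and 0.81, in a list with adjusted p = 0.187. The disproportionating enzyme DPE1 of starch breakdown rose by 0.79 (adjusted p = 0.0347; list adjusted p = 0.187). AT5G41670, a 6-phosphogluconate dehydrogenase, rose by 2.14 ± 0.16 (adjusted p = 0.00485), in an added list of 3 pentose phosphate genes. That list had a camera adjusted p = 0.203, and 0.0257 with fry, which tests whether genes move one way and not against other genes.

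The same step gave no camera call for the light-harvesting, photosystem, Calvin-Benson and photorespiration lists. With 3, 4, 4 and 3 measured genes, these lists speak for few genes of each pathway. The median was 0.06 for light-harvesting proteins, against a mean of -0.09 and a test that pointed down (adjusted p = 0.832). Medians were 0.07 for photosystem subunits (adjusted p = 0.832), -0.02 for the Calvin-Benson cycle (adjusted p = 0.881) and -0.28 for photorespiration (adjusted p = 0.810). With a common median for the arrays those of light-harvesting proteins and photosystem subunits turned to -0.01 and -0.00. RCA, Rubisco activase, read 3109 and 3105 in the low and normal CO2 groups. The reference genes AT2G28390, AT4G34270 and PEX4 had 0.18, 0.17 and -0.06 in the CO2 step and -0.49, -0.29 and -0.40 in the light step, with 0 of the 3 past the threshold (list adjusted p = 0.832 and 0.0696). Markers of other tissues and states did not pass in the CO2 step: the root gene PYK10 had -0.11, the guard cell gene FMA 0.43 and the cell division gene AUR1 0.42.

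**Figure D2:**
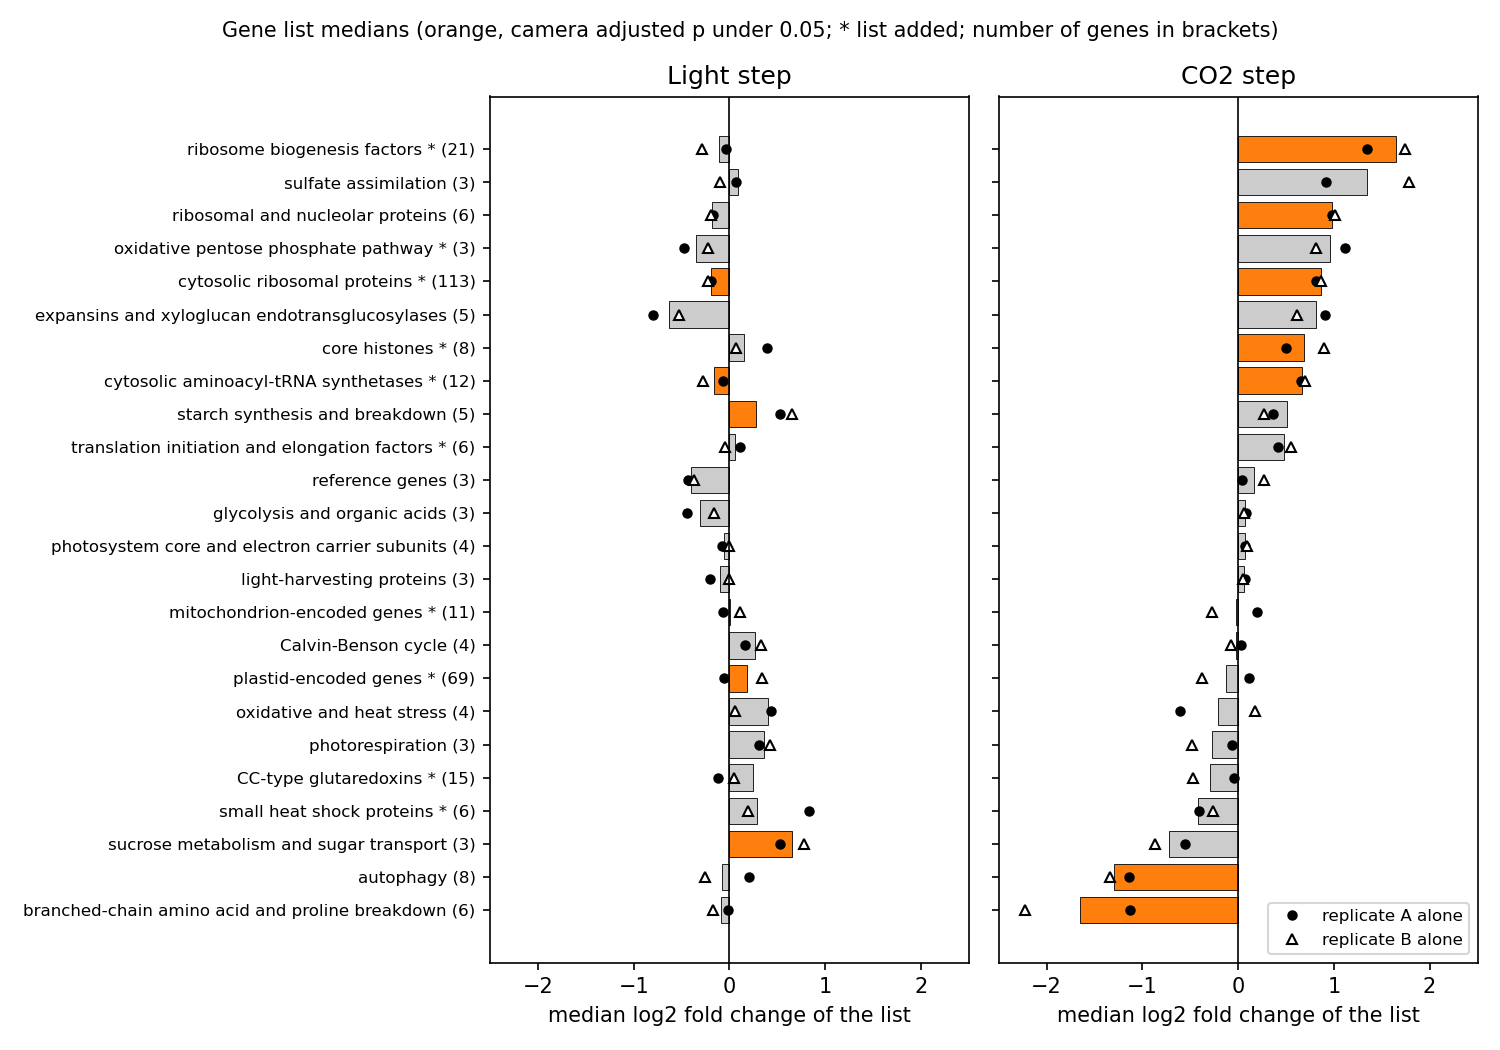
Median log2 fold change of each gene list with at least 3 measured genes in the light step and the CO2 step, with points for replicates A and B alone; orange bars passed the camera test with the preset correlation and asterisks mark lists written after the data had been seen; 0 lists passed with an estimated correlation. Ribosome biogenesis factors had the highest called median in the CO2 step (1.64) and branched-chain amino acid and proline breakdown the lowest (-1.65).

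Between low CO2 in darkness and normal CO2 in light, where both factors differed, AT3G22240 rose from 61.7 ± 0.849 to 1862 ± 281 (SD, n = 2), a log2 fold change of 4.75 ± 0.71 (adjusted p = 0.00799). AT3G44450 rose by 4.31 ± 0.22 (adjusted p = 0.00126) and AT1G06000, a flavonol rhamnosyltransferase gene, by 4.05 ± 0.21 (adjusted p = 0.00126), from a dim 1.45 in darkness. SIS fell from 1388 to 16.9, a log2 fold change of -5.85 ± 0.23 (adjusted p = 0.00121), and MCCA from 1606 ± 991 to 82.8 ± 3.46 (-4.01 ± 0.69, adjusted p = 0.0118). AT1G73600, TBL26, AT1G13650, AT5G62210, AT5G03350, AT5G59130 and AT4G12830 rose by 4.07, 3.80, 3.54, 3.41, 3.39, 3.24 and 3.24. AT1G72060, AT5G19120, AT2G20670, AT3G07350, AT4G27450, AT5G39520 and AT2G28400 fell, with -4.68, -4.19, -4.08, -4.05, -3.98, -3.94 and -3.93, and AT2G05540 fell from 1304 to 69.4. AT5G62210 started from a dim 3.90, so that the pseudocount weighs on its change, as on that of AT1G06000.

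Autophagy genes fell in this comparison in 7 of 8 cases (median -1.45, camera adjusted p = 3.59e-06, and adjusted p = 0.568 with an estimated correlation), with ATG8E at -2.41, ATG8H at -2.39 and ATG8B at -1.60. Adjusted over the list alone 8 of 8 fell. Of the breakdown genes 5 of 6 fell, both over all probe sets and adjusted over the list alone (median -2.07, adjusted p = 0.00143, and adjusted p = 0.568 with an estimated correlation). IVD fell by 3.81 on the log2 scale and ETFQO, the electron transfer flavoprotein oxidoreductase of mitochondria, by 2.32. Ribosomal and nucleolar proteins rose in 4 of 6 cases and 5 adjusted over the list alone (median 0.82, adjusted p = 0.0148, and adjusted p = 0.568 with an estimated correlation), with AT3G05060 at 1.58. Starch genes rose in 3 of 5, also adjusted over the list alone (median 1.06, adjusted p = 0.0195, and adjusted p = 0.568 with an estimated correlation). APL3, a subunit of ADP-glucose pyrophosphorylase, rose by 1.73 ± 0.38, SBE2.2 by 1.07 ± 0.13 and DPE1 by 1.06 ± 0.18. The adjusted p of the breakdown and ribosomal lists was 0.0675 and 0.0562 with fry, and that of the starch list 0.0626 after the filter on dim probe sets. The starch list lost its call without normal CO2 in light B (adjusted p = 0.0815), and the ribosomal and nucleolar list without that array (0.0898) or low CO2 in darkness A (0.0569). Of the added lists, 48 of 113 cytosolic ribosomal proteins, 20 of 21 ribosome biogenesis factors, 6 of 8 core histones and 3 of 12 aminoacyl-tRNA synthetases rose, with adjusted p = 2.61e-15, 3.97e-11, 0.000167 and 0.010. In the same order they had adjusted p = 0.688, 0.657, 0.657 and 0.688 with an estimated correlation. The synthetases lost their call after the filter on dim probe sets (0.0509) and without low CO2 in darkness A (0.105, median 0.20 against 0.34) or normal CO2 in light B (0.0859). GI rose from 31.0 to 94.3. LHCB4.3 and the glycine decarboxylase T-protein AT1G11860 rose by 0.84 and 0.62, and the isocitrate dehydrogenase cICDH fell by 0.74.

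In this comparison 2578 probe sets rose and 2077 fell, 20.5% of those tested, and with the letter as a block 2902 and 2350. With arrays shifted to a common median the majority turned, with 2139 higher and 2539 lower. The counts were 702 and 652 without normal CO2 in light A, 263 and 313 without its replicate B, and 1372 and 1205 or 1000 and 901 without low CO2 in darkness A or B. Since this contrast is the sum of the light and CO2 steps, each gene's change can be divided between these steps. No group had normal CO2 in darkness, so the CO2 step was measured in light alone and the light step at low CO2 alone. The shares belong to the steps in this order, and are not shares of CO2 and light as such. The CO2 step made up a median of 79.3% of the rises, with quartiles of 49.3% and 102%, and 68.1% of the falls, with quartiles of 44.4% and 90.9%. Of the 2578 rises, 1422 passed in the CO2 step and not in the light step, 130 the other way round, 29 in both and 997 in neither, and of the 2077 falls 993, 27, 15 and 1042. The difference between the steps itself was called for fewer of them. The CO2 step was the larger part in 101 of the rises and 122 of the falls, and the light step in 61 and 6.

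Some genes rose in one step and fell in the other, and the difference between the steps was tested for each probe set. The genes given here were chosen after their values were seen. AT1G62510 went from 157 in darkness to 1208 in light at low CO2 and back to 164 at normal CO2, a rise of 2.95 and a fall of 2.83 (adjusted p of the difference = 0.0349). AT5G43450 rose by 1.42 and then fell by 3.08 (adjusted p = 0.0176). The reverse course was that of AT5G12050, which fell by 2.40 in the light step and rose by 0.91 in the CO2 step (adjusted p = 0.0347). The light step was the higher for AT1G09500, AT1G76600, AT3G22060, AT4G16880, AT1G70820, AT3G45730, AT1G05340 and AT5G42250, and the CO2 step for BZIP61, AT5G14520, AT3G23620, AT5G41670, AT5G53770, AT4G12600, AT5G47455, AT3G07110 and AT1G06720. Higher here means the signed value, so a large fall in the CO2 step places a gene among those with the higher light step. AT1G05340, for example, had 0.45 in the light step and -3.90 in the CO2 step. The counts by sign therefore do not tell which step was larger in size. By sign, the CO2 step was the higher for 153 probe sets and the light step for 275, and with the letter as a block these counts were 318 and 505. Left-out arrays took them to 2 and 26 (low CO2 in light A), 0 and 18 (low CO2 in light B), and 1 and 37 (low CO2 in darkness B). With limma they were 0 and 0 without low CO2 in darkness A, normal CO2 in light A or its replicate B, where 3902, 4414 and 3558 had an unadjusted p under 0.05.

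**Figure D3:**
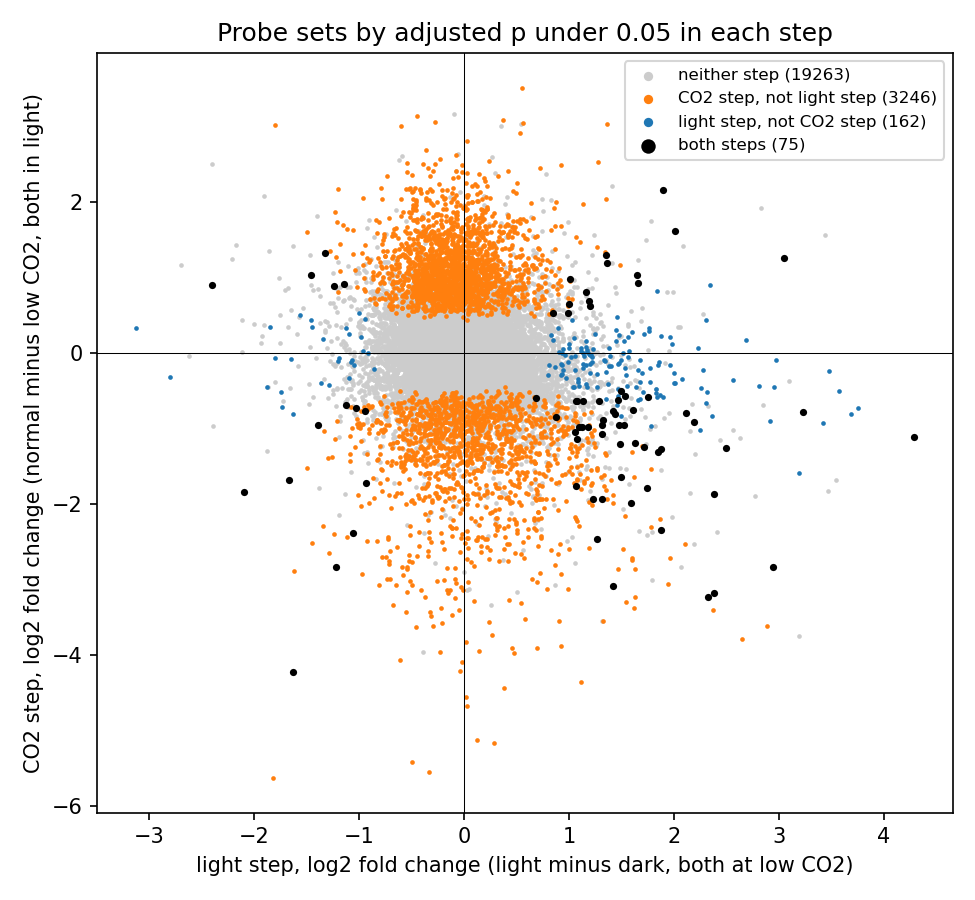
Log2 fold change of each of the 22746 probe sets in the light step (horizontal) and the CO2 step (vertical), coloured by which steps it passed at adjusted p under 0.05. The 75 probe sets past the threshold in both steps are black, and 3246 passed in the CO2 step and not in the light step.

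Across probe sets, which are not independent replicates, the fold changes of the light and CO2 steps correlated with Pearson r = -0.174 and Spearman rho = -0.198. Groups simulated without any change gave a mean Pearson r of -0.500 and rho of -0.471, because both steps contain the arrays of low CO2 in light with opposite sign. The covariance was -0.0505, against -0.0308 in the simulations, a difference of -0.0197. Within replicate A and within replicate B r was -0.244 and -0.272. It was -0.382 without low CO2 in light A and -0.0557 without low CO2 in darkness A. The genes past both thresholds, such as AT1G62510 and AT5G43450, numbered 46 for a rise in light and a fall with CO2 (11.96 for independent lists), and 5 for the reverse (3.70). Rises in both numbered 14 (16.2), AT3G44450 and XTH16 among them, and falls in both, such as SIS, WES1 and AT3G07350, numbered 10 (2.73). Simulated groups without change gave a mean of at most 0.02 in each class. Without change hardly any probe set is called in either step, so these simulations do not show how shared arrays act on overlaps of changed genes. The shared group has 2 arrays and could not be split into sets of 2, so part of these overlaps may come from the shared arrays. Fits without normal CO2 in light A or B called nothing in either step, so they are no check on the overlaps.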

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

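The control probe sets were looked at only after the data had been seen, and they entered no comparison. Of 19 probe sets for plant control transcripts, 15 read at least 100 on every array. On 10 of these both arrays of normal CO2 lay above all 4 arrays of low CO2, an order that chance gives a single probe set in 6.67% of cases. All 10 were repeat probe sets of actin or GAPDH, so they are not independent of each other and cannot be counted against that chance. Those at least 1.5-fold higher were actin and GAPDH. In the first set of controls the 3 prime actin probe set was 1.71-fold, the middle actin probe set 1.95-fold and the middle GAPDH probe set 1.52-fold higher. In the second set the 3 prime, 5 prime and middle actin probe sets were 1.92-fold, 1.93-fold and 1.94-fold higher, and the 3 prime and 5 prime GAPDH probe sets 1.54-fold and 1.63-fold. On 3 ubiquitin probe sets both arrays of normal CO2 lay below all 4 arrays of low CO2, with ratios of 0.715, 0.576 and 0.718. The 25S ribosomal RNA control read 49.1, 144.7 and 93.9 on the A arrays of low CO2 in light, normal CO2 in light and low CO2 in darkness, and 367.4, 222.4 and 352.7 on the B arrays.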

How the results depend on the processing

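Of the alternatives, the common median was run on the gene lists only after the data were seen, and the others were planned. The 160 calls of single named genes kept their direction under each alternative run on them. For the largest rises and falls named per contrast, an array left out could not reverse the direction. Their rule required both arrays of one group above both of the other. Calls of named genes lost the threshold most often without an array of normal CO2 in light, where the group left with 1 array is assumed to vary like the others. In the light step the counts higher and lower were 436 and 208 after the filter, 91 and 14 without a trend, and 0 and 0 in limma with the arrays of the compared groups alone (3445 at unadjusted p under 0.05). The count lower was 70 with a common median, 72 without a pseudocount and 27 with the larger pseudocount. With each array left out in turn these counts ran from 0 to 88 and from 0 to 11. In the CO2 step 1037 rose and 893 fell with a log2 minimum of 1, and with arrays left out 0 to 1506 and 0 to 1239. Between darkness at low CO2 and light at normal CO2 these were 1455 and 1220, and 263 to 2557 and 313 to 2138. The difference between the steps gave 45 and 129 with the larger pseudocount, 616 and 664 after the filter, 0 and 6 without a trend (4723 at unadjusted p), and 0 to 2 and 0 to 37 with arrays left out. The correlation of the steps was -0.122 after the filter and -0.382 to -0.0557 with arrays left out. Probe sets past the threshold in both steps numbered 76 in the same and 162 in opposite directions after the filter, and 0 to 8 and 0 to 30 with arrays left out. The cause of these shifts was not tested. The filter left fewer probe sets, and the fits with an array left out and of 2 groups held fewer arrays.

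The replicate letters were not taken as pairs, since there are 2 per group and deviations from the group means correlated with r = 0.0153, 0.307 and 0.159 between groups. With the replicate letter as a block 338 rose and 137 fell in the light step, the difference between the steps gave 318 and 505, and 65 and 118 probe sets passed both steps in the same and in opposite directions. The blocked fit shared 233 of the 237 calls of the light step and 3194 of the 3321 of the CO2 step, and kept 158 of 160 named genes and 20 of 20 list calls. It added 1 list call, that of plastid-encoded genes in the CO2 step (adjusted p = 0.0494).

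Of 20 list calls, 0 held with an estimated correlation, 13 with fry, 15 after the filter, 19 with quantile normalization and 20 with all probe sets of a gene averaged. The starch and sucrose lists had estimated correlations of -0.0234 and -0.388, and yet a camera adjusted p = 0.568 in the light step. At 3 residual degrees of freedom, the loss of a call there does not show that genes moving together had made it. With an estimated correlation 0 lists fixed before and 0 added lists were called in each comparison. In the light step fry called 1 list fixed before and 0 added, and the filter left 1 fixed before. In the CO2 step and between darkness at low CO2 and light at normal CO2 fry called 6 added lists each, against 4 with camera, among them translation factors (0.0228 in both) and the pentose phosphate list (0.0257 and 0.0428). Of the lists fixed before it called 3 in each, among them the sucrose list (0.0231 in both), which camera did not call there and whose median was -0.72 in the CO2 step and 0.66 in the other comparison. Fry tests whether genes move one way on balance, not against other genes. With arrays left out 0 to 2 lists fixed before were called in the light step and 2 to 4 between darkness at low CO2 and light at normal CO2. One median reversed, that of plastid-encoded genes in the light step, at -0.0367 without low CO2 in light B, in a range of -0.0367 to 0.358 with arrays left out. Detection calls are not given in the sources used here, so signal over background was not assessed per probe set, and changes among dim probe sets are the least certain.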

Other observations

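The tests of call numbers between the steps were chosen after the result was seen, as were the added lists and the families by gene symbol. Among 37 families of genes that share a symbol prefix, NRPB, subunits of RNA polymerase II, shifted up in the CO2 step (median 0.84, camera adjusted p = 0.0201, adjusted p = 0.930 with an estimated correlation, 3 of 6 past the threshold). The CYP family shifted down in the CO2 step (median -0.31, adjusted p = 0.0301, 4 of 26 fell) and up in the light step (median 0.15, adjusted p = 0.0260, 1 of 26 rose), with adjusted p = 0.930 with an estimated correlation in both. The ATG family, which shares members such as ATG8E with the autophagy list but not APG8A, shifted down in the CO2 step (median -1.12, camera adjusted p = 1.36e-05). It too had an adjusted p = 0.930 with an estimated correlation.

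Several lists had members that did not pass in the CO2 step. CHLM and PORB of chlorophyll synthesis had log2 fold changes of 0.29 and 0.48, the cytokinin regulators ARR15 and RR16 0.15 and -0.13, and WRKY53 and PDF1.2 of the wound and defence list -1.07 and -0.24. Added lists that camera did not call there were CC-type glutaredoxins (median -0.30, 1 of 15 fell), small heat shock proteins (-0.42, 0 of 6), plastid-encoded genes (-0.12, 0 of 69), mitochondrion-encoded genes (-0.02, 0 of 11) and translation factors (0.48, 1 of 6 rose and 1 fell), with adjusted p = 0.340, 0.265, 0.0793, 0.911 and 0.443. Fry, which tests whether genes move one way on balance and not against other genes, called the translation factors (adjusted p = 0.0228). With the replicate letter as a block camera called the plastid-encoded genes (adjusted p = 0.0494), whose median was 0.11 in replicate A and -0.38 in replicate B. With quantile normalization the median of mitochondrion-encoded genes was 0.01.

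The CO2 step had 3321 calls and the light step 237. At unadjusted p under 0.05 in the same limma fit the counts were 6757 and 3758. The adjusted threshold loosens as more probe sets change, so the ratio of calls overstates the difference between the steps. Larger noise of single arrays in the light step would leave the covariance between replicates A and B, which holds no such noise, at a similar size in both steps. It was 0.362 in the CO2 step and 0.126 in the light step, a ratio of 2.88 (95% bootstrap interval over probe sets 2.69 to 3.09). The fit also pooled the spread and gave both steps the same median standard error of 0.209, so such noise would weaken both tests alike. Covariances of a light step and a CO2 step that share no array differed from each other by 0.0167. The ratio of calls was 14.0 as deposited, 16.7 after quantile normalization and 10.9 with a common median, which argues against scaling between arrays. A stronger effect of CO2 than of light over these 4 hours stays a hypothesis, and differences between the chambers or plants of a treatment, which these arrays do not separate, stay open.

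Light and CO2 steps leaned in opposite directions across probe sets. The covariance of the light step in replicate A with the CO2 step in replicate B, which share no array, was 0.000496 (-0.00728 to 0.00818), and that of light in B with CO2 in A was -0.0162 (-0.0212 to -0.0107). Noise of the shared arrays of low CO2 in light may therefore account for a large part of the lean. The correlation of the steps was -0.174 as deposited and -0.177 after quantile normalization, which argues against scaling as the source of the lean as a whole. For the part without shared arrays, an effect of scaling cannot be told apart. The mean of both crossings was -0.00785 as deposited and -0.0106 after quantile normalization, where they differed by 0.0237. The bound set beforehand rested on an interval over probe sets (-0.0163 to -0.00486), which holds no noise of whole arrays. A biological opposition of light and CO2 was not tested beyond this.

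Cytosolic ribosomal proteins lay lower in light at low CO2 than in darkness and higher at normal CO2 (adjusted p = 0.688 and adjusted p = 0.657 with an estimated correlation). Of 10000 random lists matched on mean log2 intensity, 0% had a light step as low as the list's -0.20 (lowest -0.15). The median of these random lists was -0.02, which argues against brightness alone as the source of the lower value. They were drawn from unrelated genes, while the list had an estimated correlation of 0.401, so they do not test noise shared by a whole array. A single deviating array of low CO2 in light cannot be told apart, with medians of -0.19 in replicate A (-0.27 to -0.16) and -0.22 in replicate B (-0.30 to -0.17): the bound set beforehand rested on these intervals over genes, which hold no noise of whole arrays, while A minus B within low CO2 in light, normal CO2 in light and darkness was -0.17, -0.26 and -0.18. An offset between letters would give this common sign and cancel within each letter, but the letters were not taken as pairs, and across them the medians were -0.42 (light A, darkness B) and -0.03 (light B, darkness A), while the pooled -0.20 became -0.11 without low CO2 in darkness B, -0.13 without low CO2 in light A and -0.31 without low CO2 in darkness A or low CO2 in light B. That low CO2 in light may lower these transcripts stays a hypothesis, with 0 of 113 members past the threshold, and a shared property of both arrays of that group stays open too.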
